A study of Oryza sativa with 8 samples.

How the data were processed

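Poly(A) RNA from rice (Oryza sativa) roots was sequenced in 8 libraries. The labels' titles put them into 4 groups of 2 replicates, named D4_CK, D4_100X, D6_CK and D6_100X here. The treatment label reads normal for the CK libraries and names a carbon dot treatment, 100X, for the others. Carbon dots are nanometre-sized carbon particles, and the series title places them in a seed priming experiment. The labels define neither D4 and D6 nor the scale behind 100X, so these are used as names only, and nothing is assumed about days or concentrations. Nothing in the labels says that the replicates came from separate cultures or plants. The p-values therefore measure the spread between these libraries only, which may be technical.

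The deposited values are FPKM, fragment counts scaled to gene length and to the library total, for 55801 loci with LOC_Os identifiers, as computed by the authors. Per the submitters' processing notes, fastp, HISAT2, SAMtools and featureCounts 1.6.4 were used. Their settings, the genome build and the annotation are not given in the sources used here. A total of 21532 loci were at 0 in every library. Because FPKM are not counts, all tests were run on log2(FPKM + 1), and a fold change on that scale understates the change of low genes.

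Of 1115 low genes (above 0 in every library and under 0.5 FPKM), 985 (88.3%) had values that were whole multiples of a common step within 0.002 steps, and these gave the depth. The FPKM denominator came out at 22.87 M fragments in all 8 libraries, with a difference of at most 0.0098% between libraries. Of the loci above 0, 99.6% had a gene length that made all their 8 values whole numbers of reads within 0.005 reads plus a share of 3e-07 of the reads. On a gene of 1 kilobase, 1 read was worth 0.0437 FPKM. In simulated data 98.04% of the recovered lengths were right, a share that leaves out the genes with few reads.

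Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) in a single fit of the 4 group means over all 8 libraries, which share 1 estimate of the spread with 4 residual degrees of freedom. The fit covered 22794 loci with an FPKM of at least 1 in at least 2 libraries. Adjusted p-values are Benjamini-Hochberg values over these loci, and the threshold was 0.05. In all, 6 contrasts were fixed: the carbon dot effect at D4, the effect at D6, their mean, their difference (interaction), and D6 against D4 in the control and in the carbon dot groups. The script was tested on simulated data with 200 of 22794 genes changed. For the effect at D6 it called 75% of the 2-fold and 96% of the 4-fold changes, and for the effect at D4 77% and 95%. Of its 182 calls at D6 11 were false, and of its 187 calls at D4 15 were. The real D4 groups spread more than the D6 groups (median within-group SD 0.139 and 0.148 against 0.088 and 0.087, log2). The simulation recovered D4 and D6 changes alike, so its D4 shares may overstate what the real D4 libraries allow. The D6 shares may not carry over either. Of the real D6 genes changed at least 2-fold at an unadjusted limma p under 0.05, 247 were higher and 124 lower, and 53 and 16 of these passed.

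Gene lists were fixed by locus identifier or product description before the data were examined. Neither the deposited table nor the reference table used here (RefSeq genes of assembly ASM3414082v1, 39387 genes) pairs LOC_Os identifiers with names or descriptions. Some lists defined by description alone, including class III peroxidases, glutathione S-transferases, histones and the seed storage markers, were therefore not analysed here. Others, the cytokinin, jasmonate, heat shock, cell cycle, expansin and WRKY lists among them, were assembled from loci added later. Lists defined by a description and locus identifiers, the 5 lists called fixed below among them, were tested on the identifiers alone. They are parts of the lists as fixed. Names are given only for listed loci, from published locus identifiers recalled without a source at hand. Each symbol was looked up in the reference table, and it was used where the table held that symbol on the same chromosome within 0.1 chromosome lengths of the place the identifier implies. That was so for 51 of 63 loci fixed in advance. It is an indirect match, and loci without it stay in the tests but are not named. A further 167 loci were added after the table had been opened, and the 127 with a matching symbol were kept. Most were listed before any contrast was computed. The expansins, 2 single loci, several corrected symbols and the final position tolerance came after the first counts of calls had been seen. Lists with added loci are called extended below. The cytokinin, jasmonate, heat shock, cell cycle and expansin lists are among these, although they hold no locus fixed in advance.

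List tests used camera (limma) with a preset correlation of 0.01 for lists with at least 5 tested genes, and again with a correlation estimated from the residuals. Adjustment was over the 5 lists with at least 5 tested loci fixed in advance and separately over the 11 extended lists, within each contrast. The plan was to adjust over every list as fixed, so these adjusted p-values correct for fewer lists. Of the 96 list tests 11 had a median and a test direction of opposite sign, 0 of them among the 19 that passed. The 5 were cellulose synthases, reactive oxygen scavenging, nitrogen, iron acquisition and diterpenoid phytoalexins. The 11 were nitrogen, fermentation, aquaporins, phosphate starvation, dehydration and abscisic acid, auxin, cytokinin, jasmonate, heat shock, cell cycle and expansins. Smaller lists (crown root factors, ethylene synthesis, WRKY factors, pathogenesis-related, potassium and sodium transport, sucrose synthases and amylases, housekeeping, photosynthesis) were described by their counts alone.

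Genes were named by a rule fixed before the data were examined. Its first part needed a descriptive product name, which no source used here gives, so it named no gene by function. At most 2 identifiers in each direction are printed per carbon dot contrast in its place. They have the largest fold changes among genes past the threshold whose libraries do not overlap and whose mean reaches 5 FPKM in any group. The rule as fixed asked for that mean in the higher group compared, which LOC_Os10g02509 does not reach at D6 (4.63 FPKM). Its second part named from each list the 2 members with the largest change among those past the threshold, and the 2 most abundant members of lists whose camera test passed. Other members named were chosen after their values were seen.

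Alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median centring of the libraries, robust eBayes, the replicate number as a block, leaving out each library in turn, and fits of only the 4 libraries compared. Chosen after seeing the data were limma voom on the recovered reads and a replicate term for D4 alone. Tables were made with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures with Matplotlib 3.10.9.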

Results

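The root transcriptomes of 4 groups of rice were compared, namely controls and carbon dot samples at D4 and at D6, with 2 libraries in each group. The FPKM denominator inferred from the values was 22.87 M fragments in all 8 libraries, and between 28619 and 30252 loci were above 0. Between 21428 and 21546 loci reached 1 FPKM in each library, and the 10 most abundant loci held 4.0% to 4.94% of the summed FPKM. Photosynthesis genes, which mark green shoot tissue, stayed at or below 1.98 FPKM in every library, and none of the 9 listed passed the expression filter.

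The libraries were first compared with each other across the 22794 tested loci. D4 and D6 libraries separated along the first principal component, which held 66.5% of the variance. At D6 the replicates of a group were closest to each other, with r = 0.987 in the controls and 0.988 in the carbon dot group, against 0.972 to 0.974 between them. At D4 they were not. Libraries of the same replicate number correlated at 0.985 and 0.990 across treatments, above the 0.975 between the 2 controls and the 0.966 between the 2 carbon dot libraries. These are correlations across genes, which are not independent replicates. The median within-group SD (log2) was 0.139 and 0.148 in the D4 control and carbon dot groups, and 0.088 and 0.087 in those at D6.

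**Figure D1:**
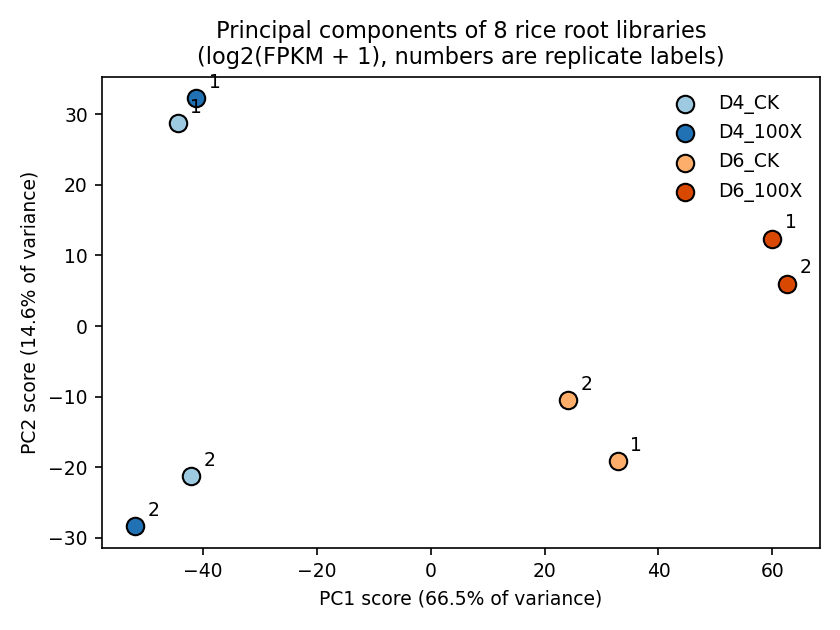
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1), with axes in score units and the share of variance in brackets, colours for groups and numbers for replicates. The D6 groups lie apart by treatment, whereas the D4 libraries lie apart by replicate number on the component that holds 14.6% of the variance.

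At D6, the question was which root genes differed between carbon dot and control samples. The transcripts of cellulose synthases, the enzymes that spin cellulose into the cell wall, were lower in the carbon dot roots as a list, with a median log2 fold change of -0.69 over the 6 tested genes and all 6 below 0 (camera adjusted p = 2.61e-05 over the fixed lists; adjusted p = 0.318 with an estimated correlation). The secondary wall genes CESA4, CESA7 and CESA9 had the lowest ratios. CESA4 averaged 49.3 ± 12.2 FPKM (SD, n = 2) against 90.2 ± 8.99 in the controls, CESA7 55.8 ± 12.1 against 103.5 ± 13.9, and CESA9 45.9 ± 14.4 against 86.7 ± 10.7. Among the primary wall genes, CESA1 averaged 143 ± 2.86 FPKM against 202 ± 4.95, and CESA8 143 ± 4.64 against 186 ± 0.845. None of the 6 passed adjusted over all genes (adjusted p for CESA1 = 0.0954), whereas 5 of 6 passed adjusted over the list alone, CESA3 being the exception.

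Wall-loosening expansins were also lower as a list in the carbon dot roots at D6 (10 genes of an extended list, median log2 fold change -0.43, camera adjusted p = 0.0296, and 0.482 with an estimated correlation). Of the 10, 3 had positive fold changes, and the list was drawn up after the first counts of calls had been seen. EXPB2 averaged 33.3 ± 9.02 FPKM against 73.0 ± 17.5 in the controls. The most abundant members were EXPB6, at 115 ± 7.19 against 176 ± 19.5 FPKM, and EXPB4, at 144 ± 16.01 against 172 ± 2.56 FPKM. No expansin passed over all genes, and EXPB2 and EXPB6 passed adjusted over the list alone. This list's call was lost without D6_CK replicate 2 (adjusted p = 0.140) and without D6_100X replicate 1 (adjusted p = 0.0757). All 12 tested cell cycle genes had negative fold changes, with a smaller median of -0.23 (camera adjusted p = 0.00155; adjusted p = 0.573 with an estimated correlation). They included PCNA, the DNA replication clamp, at 69.6 ± 2.87 against 83.3 ± 1.43 FPKM, and the mitotic kinase gene CDKB2-1 at 42.7 ± 0.281 against 50.8 ± 0.772 FPKM. No cell cycle gene passed on its own under either adjustment.

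The listed gene past the threshold over all genes at D6 was HSP17.9A, a small heat shock protein gene, which rose to 22.9 ± 3.88 FPKM from 6.85 ± 0.538 (log2 fold change 1.6 ± 0.14 SE, limma adjusted p = 0.0227). Its adjusted p was 0.211 without D6_CK replicate 1, 0.144 without D6_CK replicate 2, 0.145 without D6_100X replicate 1, 0.198 without D6_100X replicate 2 and 0.0504 without a filter. The heat shock list did not move as a whole (7 genes tested, 1 rose, median log2 fold change 0.07, camera adjusted p = 0.236). Adjusted over the list alone, HSFA2C, a heat stress transcription factor gene, also passed upwards and HSP17.7 downwards. Among auxin genes, IAA20, which encodes an Aux/IAA repressor, stood at 35.3 ± 12.4 FPKM against 10.9 ± 1.13 in the controls (log2 fold change 1.57 ± 0.24, adjusted p = 0.0549 over all genes and 0.00704 over the list alone). CKX4, which encodes a cytokinin-degrading oxidase, stood at 6.14 ± 0.039 against 1.86 ± 0.142 FPKM (adjusted p = 0.0809 over all genes and 0.00767 over the list alone). The cytosolic glutamine synthetase gene GS1-1 was at 381 ± 6.04 against 539 ± 24.0 FPKM (adjusted p = 0.104 over all genes and 0.0202 over the list alone). Adjustment over a list alone, here and below, does not correct for the number of lists. All loci of the heat shock list, HSP17.9A included, and IAA20, CKX4 and GS1-1 were added after the table had been opened. Of the 22794 tested loci 3603 had an unadjusted limma p under 0.05 at D6.

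The remaining lists did not pass at D6, with camera adjusted p-values of 0.968 for reactive oxygen scavenging, 0.671 for nitrogen (0.126 extended), 0.671 for iron acquisition, 0.647 for diterpenoid phytoalexins, 0.421 for fermentation, 0.772 for aquaporins, 0.617 for phosphate starvation, 0.236 for dehydration, 0.434 for auxin, 0.421 for cytokinin and 0.236 for jasmonate genes. No member of the WRKY, ethylene synthesis, potassium and sodium transport, sucrose synthase and amylase, crown root, pathogenesis-related or housekeeping lists passed over all genes. Of the 2 crown root loci, 1 whose symbol was not matched passed downwards adjusted over the list alone, with a log2 fold change of -0.94. A nitrogen locus without a matched symbol passed upwards in the same way.

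Over all genes, 119 passed the limma threshold at D6, of which 92 were higher and 27 lower in the carbon dot roots. LOC_Os12g33150 rose to 18.7 ± 1.65 FPKM from 1.39 ± 0.722 (log2 fold change 3.07 ± 0.22, adjusted p = 0.0209), and LOC_Os01g73250 rose to 44.1 ± 6.74 from 4.40 ± 1.22 (3.07 ± 0.20, adjusted p = 0.0208). LOC_Os01g11730 fell to 12.8 ± 1.32 FPKM from 63.86 ± 17.89 (-2.21 ± 0.19, adjusted p = 0.0227), and LOC_Os10g02509 fell to 0.613 ± 0.269 from 4.63 ± 0.986 (-1.80 ± 0.20, adjusted p = 0.0350). The number of calls was fragile. It was 0 without D6_CK replicate 1, 5 without D6_CK replicate 2, 0 without either D6_100X library, 22 without either D4_CK library, 230 and 231 without D4_100X replicates 1 and 2, and 697 when only the 4 D6 libraries were fitted. A pseudocount of 0.1 gave 16 calls, no filter 11 and the replicate block 11. The replicate term within D4 only, chosen after the data were seen, gave 1400.

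**Figure D2:**
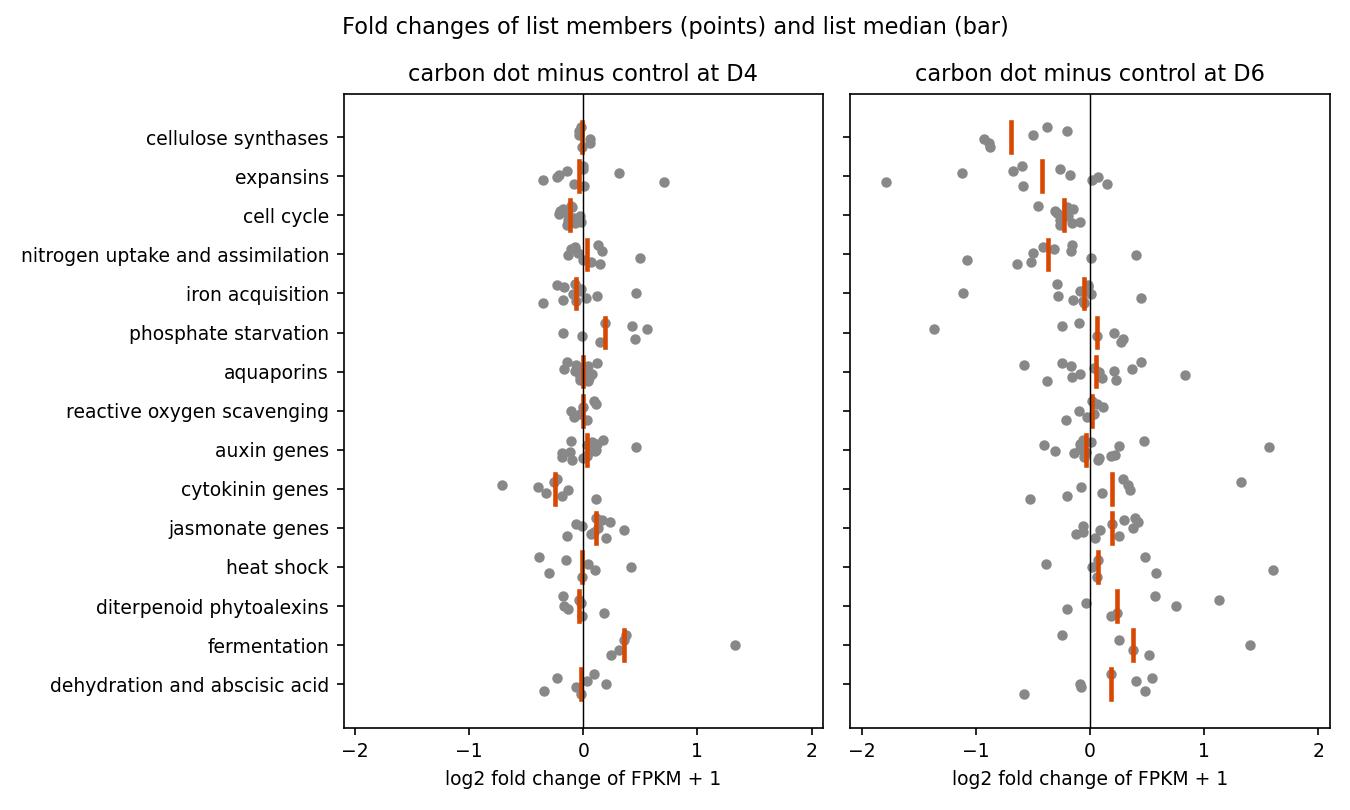
Log2 fold changes of FPKM + 1 (carbon dot minus control) of the tested members of 15 gene lists at D4, left, and D6, right, with a point per gene and a bar at each list's median, extended lists being shown where they exist. All 6 cellulose synthases lie below 0 at D6, with a median of -0.69, while at D4 their median is -0.015.

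At D4, the same question was asked, and no gene passed the limma threshold. At an unadjusted p under 0.05 there were 432 genes, where 0.05 of the tested loci comes to 1140. That number was 944 without D4_CK replicate 2, 1284 without D4_100X replicate 1 and 1175 without D4_100X replicate 2, each with 0 genes past the threshold, and limma voom on the recovered reads called 0 as well, with 343 at an unadjusted p under 0.05. Without a filter 2 genes passed, both lower with carbon dots. The median log2 fold change of the cellulose synthases was -0.015 (camera adjusted p = 0.968). CESA4 averaged 203 ± 43.8 FPKM in the carbon dot roots and 203 ± 28.1 in the controls. HSP17.9A was at 4.35 ± 0.0597 against 3.99 ± 0.269 FPKM, and IAA20 at 11.4 ± 2.23 against 8.01 ± 0.715 FPKM.

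Of the gene lists, 4 extended ones passed the preset camera test at D4, and none did with an estimated correlation (adjusted p = 0.573 for all 4). Fermentation genes were higher, with a median log2 fold change of 0.36 over 5 genes (camera adjusted p = 0.0207). The pyruvate decarboxylase gene PDC1 stood at 40.3 and 0.818 FPKM in the 2 carbon dot libraries and at 4.26 and 1.25 FPKM in the controls, and PDC2 and the alcohol dehydrogenase gene ADH2, the most abundant members, averaged 236 ± 100 against 175 ± 6.08 and 195 ± 55.5 against 156 ± 39.2 FPKM. Without D4_100X replicate 1 the direction of this list turned (adjusted p = 0.937), and the call was lost without D4_CK replicate 1 (0.256) and without D4_CK replicate 2 (0.0779). Cytokinin genes were lower (8 genes, median -0.25, camera adjusted p = 0.00374), with the response regulator gene RR10 at 16.2 ± 8.41 against 26.1 ± 8.28 FPKM, and this call was lost without D4_CK replicate 2 (0.2002) and without D4_100X replicate 1 (0.597). The most abundant cytokinin members, RR2 and RR4, had log2 fold changes of -0.19 and -0.33.

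Jasmonate genes were higher at D4 (11 genes, median 0.11, camera adjusted p = 0.0237), and the call was lost without any single D4 library (adjusted p of 0.123, 0.159, 0.205 and 0.210). The most abundant, TIFY10B and OPR7, had log2 fold changes of 0.13 and 0.09. Cell cycle genes were lower by a median of -0.12 over 12 genes (camera adjusted p = 0.00374), and the call was lost without D4_CK replicate 1 (0.745) and without D4_100X replicate 2 (0.459). PCNA stood at 65.6 ± 0.939 against 72.5 ± 7.51 FPKM. The other lists did not pass, with camera adjusted p-values of 0.968 for the reactive oxygen, nitrogen, iron and diterpenoid lists, 0.144 for phosphate starvation, 0.697 for expansins, and 0.986 for extended nitrogen, aquaporins, dehydration, auxin and heat shock.

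The effects at D4 and D6 were then set against each other. The fold changes correlated across genes at -0.069, between comparisons that share no library. The difference itself was tested as an interaction, and 2 genes passed. LOC_Os01g71350 was at 1.201 ± 0.0971 against 1.36 ± 0.121 FPKM at D4 and at 53.3 ± 0.484 against 8.08 ± 1.48 at D6, carbon dots against control (difference of log2 fold changes 2.69 ± 0.20, limma adjusted p = 0.0397). LOC_Os10g02509 was at 6.25 ± 1.02 against 0.655 ± 0.149 FPKM at D4 and at 0.613 ± 0.269 against 4.63 ± 0.986 at D6 (-3.93 ± 0.28, adjusted p = 0.0397). Both calls were lost without any single library of the 8, with a pseudocount of 0.1, without a filter, with a mean FPKM of at least 5, under median centring and with voom. Robust eBayes kept both, and the replicate block called 0 genes. The replicate term within D4 only called 100, both included, but was chosen after the data were seen. As a list, the cellulose synthases had a lower effect at D6 than at D4 (median difference -0.66, camera adjusted p = 7.69e-05; adjusted p = 0.365 with an estimated correlation), and 5 of 6 passed adjusted over the list alone. No other list passed the test of the difference, the next being cytokinin genes at an adjusted p of 0.141.

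Averaged over D4 and D6, no gene passed the limma threshold for the carbon dot effect, with 2145 at an unadjusted p under 0.05. Voom also called 0 (1973 unadjusted), as did the replicate term within D4 only (4130 unadjusted). Without D4_100X replicate 2 there were 3. Cellulose synthases were lower (median -0.34, camera adjusted p = 9.04e-05), as were cell cycle genes (median -0.18, 3.88e-05) and expansins (median -0.24, 0.0102), while jasmonate genes were higher (median 0.12, 0.0458). With an estimated correlation the adjusted p-values were 0.373, 0.509, 0.345 and 0.509. The jasmonate call was lost without D4_CK replicate 1 (0.0726), D4_100X replicate 2 (0.0804), D6_CK replicate 2 (0.231) or D6_100X replicate 1 (0.314). The remaining 12 lists did not pass.

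**Figure D3:**
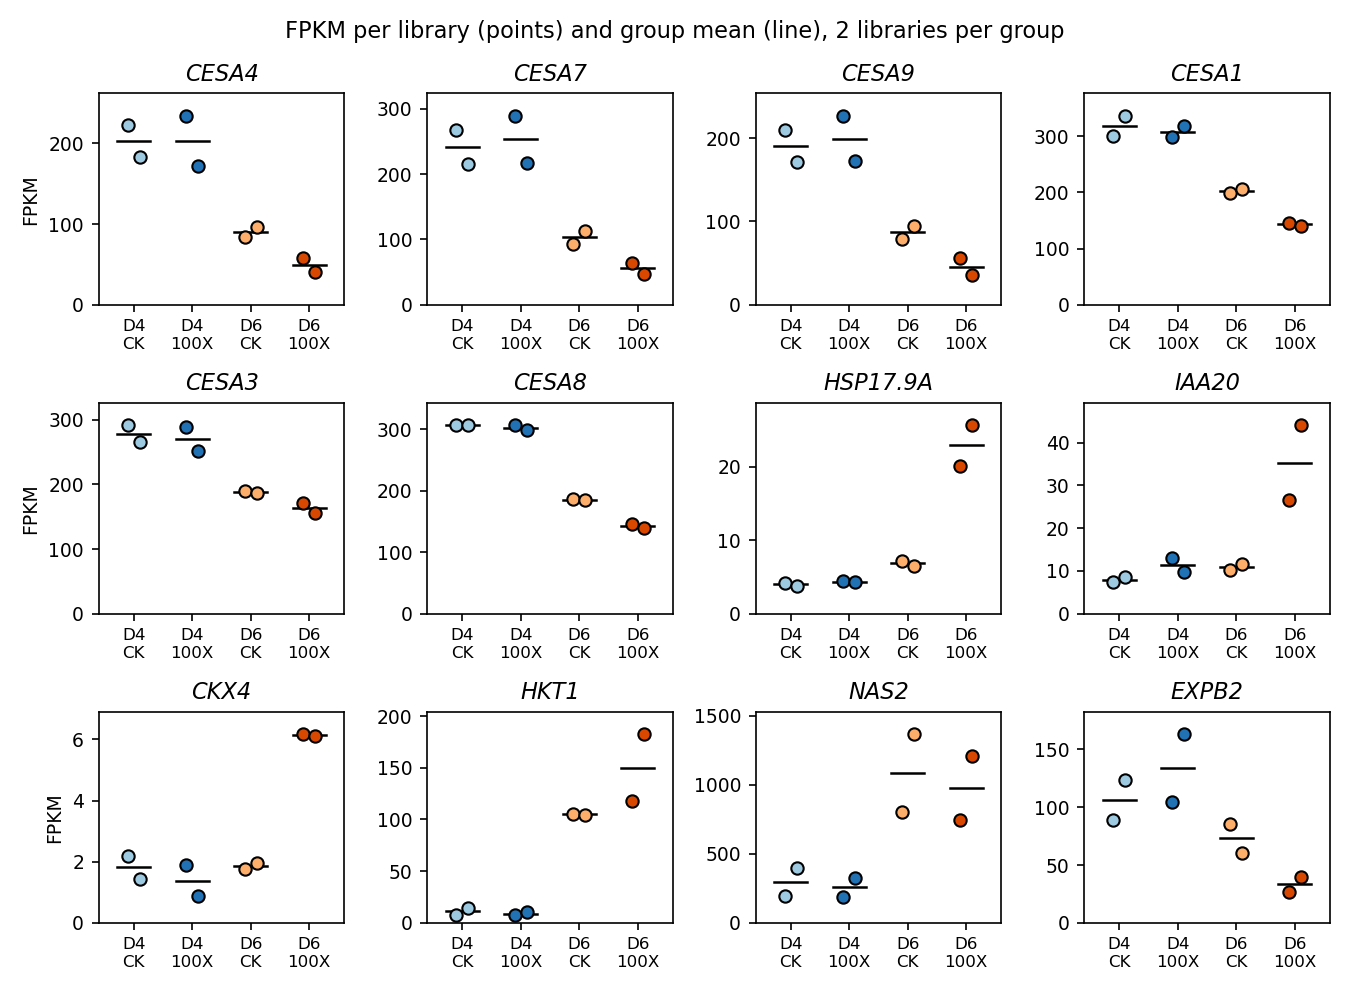
FPKM in each of the 8 libraries (points) and group means (lines) for 12 list members named in the text, on axes that start at 0, with CK for controls and 100X for carbon dots. The 6 CESA genes are lower at D6 than at D4 and lowest in the D6 carbon dot libraries, and HSP17.9A is highest there at 22.9 FPKM on average.

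The comparison of D6 with D4 in the controls asked which genes differ between these samplings without treatment. All 6 cellulose synthase genes were lower at D6, with log2 fold changes from -0.56 for CESA3 to -1.21 for CESA7 (adjusted p = 0.0295 and 0.0207), and CESA4 fell from 203 ± 28.1 to 90.2 ± 8.99 FPKM. Some listed transporter genes were higher, although the nitrogen list did not pass and 5 of the 7 phosphate genes did not pass over all genes. HKT1, which encodes a sodium and potassium transporter, rose from 10.96 ± 4.55 to 104.9 ± 0.317 FPKM (log2 fold change 3.2 ± 0.31, adjusted p = 0.00652), and the 3 tested potassium and sodium transport genes all rose. The phosphate transporter gene PHT1-1 rose from 27.4 ± 0.0439 to 68.4 ± 19.4 FPKM (1.26 ± 0.18, adjusted p = 0.0125), and NIP2-1, the silicon influx channel gene, from 235 ± 85.1 to 639 ± 12.1 (1.49 ± 0.27, adjusted p = 0.0223), while the tonoplast aquaporin gene TIP2-1 fell from 1071 ± 54.3 to 519 ± 39.1 FPKM (-1.05 ± 0.20, adjusted p = 0.0260).

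Nicotianamine synthase genes serve iron uptake, and of the 3 tested only NAS2 passed over all genes. It rose from 298 ± 143 to 1086 ± 397 FPKM (1.90 ± 0.46, adjusted p = 0.0480), and its near-identical neighbour NAS1, with which it may share reads, went from 296 ± 129 to 867 ± 253 (adjusted p = 0.0532), while NAS3 was at 34.9 ± 11.2 against 25.2 ± 4.74 FPKM (adjusted p = 0.315). Of the 12 tested iron genes 1 rose and 2 fell over all genes, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.446 with an estimated correlation). The iron call was lost without D4_CK replicate 1 (0.1004) and without D6_CK replicate 2 (0.0815). All 7 phytoalexin genes of the diterpenoid list had positive fold changes (median 1.28, camera adjusted p = 0.00310; adjusted p = 0.411 with an estimated correlation), with 0 past the threshold over all genes and 3 adjusted over the list alone. CPS4, a momilactone pathway cyclase gene, was at 23.8 ± 4.46 against 5.48 ± 5.47 FPKM, and MAS, the momilactone synthase gene, at 30.2 against 8.13 FPKM on average. That call was lost without D4_CK replicate 1 (0.0916).

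Among the extended lists, phosphate starvation (7 genes, 2 rose, median 1.11) and jasmonate genes (11 genes, 2 rose, median 0.43) passed in the controls with the same camera adjusted p of 0.000851, and neither with an estimated correlation (adjusted p = 0.549 for both). The phosphate signalling gene SPX2 rose from 2.52 ± 0.645 to 6.55 ± 0.525 FPKM, and PHT1-8, the most abundant member, was at 147 against 61.2 on average. TIFY11C and TIFY11D, which encode jasmonate-response repressors, rose from 20.4 ± 0.536 to 47.4 ± 12.1 and from 11.3 ± 0.096 to 24.7 ± 6.47 FPKM, and the most abundant TIFY10B and OPR7 had log2 fold changes of 0.34 and 0.10. Of single members, WRKY62 (log2 fold change 1.98), ADH2 (1.41), HAK1 (1.81), AKT1 (0.48), CKX5 (0.66) and HSP17.9A (0.65) rose and IAA10 (-0.47) fell. An unmatched crown root locus also fell. Adjusted over the list alone, 4 phosphate, 3 jasmonate and 4 WRKY genes rose, 4 cytokinin and 3 expansin genes fell, and 2 reactive oxygen genes and 1 expansin gene rose. The lists that did not pass had camera adjusted p-values of 0.301 for reactive oxygen scavenging, 0.0828 for nitrogen (0.106 extended), 0.577 for fermentation, 0.991 for aquaporins, 0.240 for dehydration, 0.590 for auxin, 0.229 for cytokinin, 0.829 for heat shock, 0.716 for cell cycle and 0.577 for expansins.

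In total 2311 genes differed between D6 and D4 in the controls, 1236 higher and 1075 lower at D6. The number was 372 and 1412 without D4_CK replicates 1 and 2, 60 and 657 without D6_CK replicates 1 and 2, 1127 and 1135 without D6_100X replicates 1 and 2, 2904 and 2911 without D4_100X replicates 1 and 2, and 1292 when only the 4 control libraries were fitted. It was 1446 without a filter, and 5170 with the replicate term within D4 only, which was chosen after the data were seen.

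The comparison of D6 with D4 was repeated in the carbon dot groups, where 6789 genes passed, 3309 higher and 3480 lower at D6. All 6 cellulose synthases fell here too, with log2 fold changes from -0.72 for CESA3 to -2.16 for CESA7 (adjusted p = 0.00521 and 0.00122; camera adjusted p for the list = 3.18e-05, and 0.326 with an estimated correlation, as in the controls). The difference from the fall in the controls is the interaction, which none of the 6 passed over all genes (adjusted p from 0.436 to 0.820). EXPA17 fell by 3.04 on the log2 scale (SE 0.65, adjusted p = 0.0151) and EXPB3 by 2.02 (SE 0.37, adjusted p = 0.00890), and in all 2 expansins rose and 5 fell. HKT1 rose from 8.63 ± 1.94 to 150 ± 45.6 FPKM (3.95 ± 0.31, adjusted p = 0.000703). Of the aquaporins 4 rose, among them PIP1-3 (1.77 ± 0.29), and 3 fell, among them TIP2-1 (-1.56 ± 0.20). Of the iron genes 7 rose, with NAS2 at 975 ± 325 against 258 ± 96.5 FPKM, and 2 fell (camera adjusted p = 0.102). Adjusted over the list alone, 8 iron genes rose and 2 fell, 4 aquaporin genes rose and 4 fell, and 2 expansin genes rose and 6 fell.

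The diterpenoid phytoalexin list was higher in this comparison too (median 1.89, 3 of 7 rose over all genes and 6 adjusted over the list alone, camera adjusted p = 0.00654; adjusted p = 0.687 with an estimated correlation, and 0.0691 without D4_100X replicate 1). CYP99A3, a momilactone pathway P450 gene, rose by 2.87 ± 0.55, CPS4 by 2.43 ± 0.62 and KSL7 by 1.95 ± 0.55 on the log2 scale. Of the 4 WRKY genes 3 rose, with WRKY62 at 28.9 ± 2.52 against 5.10 ± 2.47 FPKM, and the pathogenesis-related gene PBZ1 rose from 30.8 ± 9.47 to 93.3 ± 16.97. The members that follow stand against 6789 of 22794 tested loci called here, and none of the camera-tested lists they come from passed. Hormone genes went both ways. CKX4 (1.62) and CKX5 (1.18) rose and RR1 (-1.41) and RR2 (-0.56) fell. IAA20 (1.51) and the auxin-conjugating GH3.8 (1.37) rose and IAA24 (-0.91) fell, and of the jasmonate genes 5 rose, including AOS2 (1.85) and TIFY11D (1.31). Of the 7 heat shock genes, HSP17.9A (2.15) and HSFA2C (0.75) rose and HSP17.7 (-0.51) fell. PHT1-1 (1.64) and SPX2 (0.95) rose, ADH2 (1.48) rose, PDC3 (-1.52) fell, and the stress gene SALT rose by 1.23. CATB (0.54) and APX2 (0.59), which encode peroxide-removing enzymes, rose and CATA (-0.70) fell. Of the 10 genes of the extended nitrogen list 1 rose, a locus without a matched symbol (0.89), and 1 fell, GS1-1 (-0.45). MCM7 (-0.43), the ethylene synthesis gene ACS5 (-1.11), and the actin gene ACT1 (-0.48), often used as a reference, fell.

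Other lists did not pass in the carbon dot groups, with camera adjusted p-values of 0.524 for reactive oxygen scavenging, 0.688 for nitrogen (0.955 extended), 0.850 for fermentation, 0.955 for aquaporins, auxin and cytokinin genes, 0.0539 for phosphate starvation, 0.0508 for jasmonate, 0.122 for dehydration, 0.531 for heat shock, 0.276 for cell cycle and 0.316 for expansins. The sucrose synthase genes SUS1, SUS2 and SUS4 passed in neither D6 to D4 comparison. The number of genes called was 3076 and 2862 without D6_100X replicates 1 and 2.

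Calls of the 2 D6 to D4 comparisons, which share no library, overlapped. A total of 1124 genes were higher at D6 in both, where independent lists would share 179.4, and 992 were lower in both, against 164.1. In opposite directions 3 genes were called. Both comparisons use the same spread estimate of each gene, so their calls are not independent. The 192 genes called in the controls alone and the 4670 called in the carbon dot groups alone are not shown to differ between treatments, since that difference is the interaction above, which 2 genes passed in the limma fit of the 4 group means.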

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

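The interaction tests were fixed in advance, and the tests of explanations in this part were all chosen after the result was seen.

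The carbon dot effect differed between D4 and D6, by a test of the difference itself, for 2 genes and 1 gene list. The difference of log2 fold changes, D6 minus D4, was 2.69 for LOC_Os01g71350 and -3.93 for LOC_Os10g02509, and the median over the 6 cellulose synthase genes was -0.659. LOC_Os10g02509 was higher with carbon dots in both D4 libraries and lower in both D6 libraries. Both gene calls were lost without any 1 of the 8 libraries, while the cellulose synthase call held without each of them and was lost with an estimated correlation (adjusted p = 0.365).

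The D4 libraries resembled each other by replicate number more than by treatment. The SD across genes of the difference between numbers 1 and 2 was 0.384 at D4, against 0.201 for the carbon dot effect there. A difference in progress along the change from D4 to D6 was argued against, because the difference between numbers correlated at only -0.076 across genes with that change in the controls and at 0.103 in the carbon dot groups. An exchange of treatment labels between 2 D4 libraries could not be decided. Of the 119 genes called at D6, 71 (59.7%) had the same sign in D4 number 1 minus number 2, short of what a shared effect would give and above an even share, and the correlation across genes with the D6 effect was 0.296, against -0.069 for D4 as labelled. With the labels of D4_CK replicate 1 and D4_100X replicate 2 exchanged, a fit of 4 libraries against 4 with a term for D called 1589 genes, against 0 as labelled and at most 1 in the other splits. The larger spread between numbers at D4 would enter that count whatever its source. It was not enough for calls by itself. The split with the same D4 grouping and the D6 groups the other way round called 0 genes. That split still had 3443 genes at an unadjusted p under 0.05, against 5384 with the labels exchanged and 1459 as labelled. The share of signs assumes that the effect at D4 resembles that at D6, which nothing here shows. A growth or culture difference between the D4 samples was not tested. If labels were exchanged, the absence of calls at D4 and for the mean effect may not hold. The interaction results and the D6 against D4 comparisons may then not hold either. Fold changes at D6 would stay as they are, but the number of calls there could change, since all groups share 1 spread estimate. It was 1400 rather than 119 with the replicate term within D4 only.

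Genes that differed with carbon dots at D6 tended to move the same way from D4 to D6 in the controls. Of the 92 higher genes 89 had a positive change there and 60 were called higher (5 if the calls were independent). Of the 27 lower genes 19 had a negative change and 16 were called lower (1.3 if independent). The calls are not independent, since both comparisons use the same spread estimate of each gene. The comparisons share the D6 control libraries, which would by itself give a negative covariance (-0.0244 in simulated data). The observed covariance was 0.0501, and it was 0.0519 and 0.0884 with a different D6 control library in each comparison. Chance values of the shared libraries are therefore argued against. A gene length trend is argued against as well, with a correlation of -0.03 across genes between the D6 effect and log2 length. A candidate explanation is that the carbon dot roots were further along the change seen between D4 and D6. It stays a hypothesis, since differences in sampling, growth stage or culture were not tested and cannot be separated from the treatment with 1 pair of libraries per group.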

How the results depend on the processing

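The replicate term for D4 alone, voom on the recovered reads, and the list tests with a block or without single libraries were chosen after the result was seen, and the other alternatives were fixed in advance. Numbers of genes called follow. For the carbon dot effect at D4 (0), no filter gave 2 (1112 unadjusted) and the other alternatives and each left-out library 0, with 1112 unadjusted also for the replicate term within D4 only. For the effect at D6 (119), a pseudocount of 0.1 gave 16, no filter 11, the replicate block 11, the replicate term within D4 only 1400 and the 4 D6 libraries alone 697, and leaving out libraries gave 0 to 231. The 1400 and 697 each include all 119. The mean effect (0) stayed at 0 except for left-out libraries (0 to 3). The interaction (2) gave 0 with a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median centring, the replicate block, voom and every left-out library (0 to 0), and 100 with the replicate term within D4 only. D6 against D4 in the controls (2311) gave 1446 without a filter, 5170 with the replicate term within D4 only, 1292 with the 4 control libraries alone and 60 to 2911 with left-out libraries. In the carbon dot groups (6789) left-out libraries gave 2862 to 6766, and other alternatives stayed within 1.5 times. The cause was not tested, though left-out libraries and 4-library fits have fewer samples and the term at D4 removes spread between numbers. Fewer samples would not by themselves raise the D6 count to 697. That fit leaves out the D4 groups, whose median within-group SD (0.139 and 0.148) exceeded that of the D6 groups (0.088 and 0.087). Where a group keeps 1 library, it is assumed to vary like the others. The replicate numbers are not known to pair the libraries. Deviations from the group means correlated across genes at 0.602 between same-numbered D4 libraries and at -0.112 at D6. That argues against a batch shared by all libraries of a number. Of the 8 libraries 4 had their best match outside the group under their own number, all of them D4 libraries. The block gave 22 list calls. Of the 96 list tests 19 passed, 0 with an estimated correlation, 19 with centring and 17 to 27 with left-out libraries. The fermentation list at D4 turned direction without D4_100X replicate 1 (adjusted p = 0.9367), with a range of 2.343e-05 to 0.9367 over left-out libraries. Of 2256 recomputed values of 135 gene results, 1859 kept their side of the threshold, 397 no longer passed and 0 turned. At the depth here 1 read on 1 kilobase is 0.0437 FPKM, and less on a longer gene.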

Other observations

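The counts over other splits of the libraries were chosen after the result was seen.

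No gene passed for the mean carbon dot effect, which sets 4 libraries against 4, with 2145 genes at an unadjusted p under 0.05 in the limma fit of 4 groups and 1459 in a fit of the split with a term for D. All 34 of the 34 splits that such a fit can separate from D, the real one included, gave at least as many genes, which a real count of 0 fixes in advance, so this number decides nothing. The highest other split called 1589 genes and set the D4 libraries of number 1 and the D6 carbon dot libraries against the D4 libraries of number 2 and the D6 controls. The split with the D6 groups the other way round called 0 genes, with 3443 at an unadjusted p under 0.05. The 1589 calls point to a structure of the samples, and this split is also the grouping that 1 of the 4 possible exchanges of a D4 control with a D4 carbon dot library would give.

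The FPKM denominators of the 8 libraries lay between 22.8659 M and 22.8681 M fragments, a closeness that independent sequencing runs would not be bound to give. The values do not show how it came about, and the processing step behind it is not given in the sources used here.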
